A study of Mus musculus with 4 samples.

How the data were processed

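RNA was measured in 4 libraries of mouse E14 embryonic stem cells, 2 of wild-type cells and 2 of cells targeted at Ssrp1 with CRISPR/Cas9, all grown in serum with LIF. Per the labels' protocols, total RNA was treated with DNase, ribosomal RNA was depleted with Ribo-Zero, and cDNA was primed with random primers in the presence of actinomycin D and sequenced from both ends. The series describes the libraries as strand-specific. Per the submitters' processing notes, cutadapt, HISAT2 and featureCounts were used with the mm10 genome build. Their versions, the annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. The deposited values are whole-number counts per gene symbol with no normalization, in 1 table of 55353 symbols. Of these, 26633 had 0 counts in all 4 libraries. The table's column names carry the letters OK where the sample titles carry KO; gene, role and number fit a single sample in each case, and the columns were mapped on that basis. Columns not mapped to a sample numbered 0.

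How counting was done affects what can be read from the values. Genes with near-identical copies, such as the Zscan4, Usp17l, Rhox, Xlr, histone and ribosomal protein families, may have gained or lost reads to each other. If strand was not used in counting, overlapping and antisense genes would share reads too. Depletion of ribosomal RNA can differ between libraries, and reads left from it can be counted at the ribosomal-RNA-like genes Gm26917 and Gm42418. The share of these genes differed between the groups, and the cause was not tested. Random priming keeps RNAs without a poly(A) tail, such as replication-dependent histone transcripts, in the libraries.

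Gene positions and types were taken from GENCODE M21, which is on the same build. Of the 55353 symbols, 53347 matched 1 gene by name, 997 were matched through the RefSeq table of GRCm38.p6, 114 matched several genes and 895 matched none; the last 2 kinds have no position here. Total counts ranged from 22611434 to 25344190 per library, so that 3 counts, the floor used where a group had none, correspond to between 0.123 and 0.136 CPM in a single library. Folds against a group with no count are bounds against 3 counts over the group. Where a group had 1 to 3 counts, the ratio of summed, scaled counts is given with an exact (Clopper-Pearson) 95% interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

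Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15) in R 4.3.3, which left 17482. Libraries were scaled by TMM, and the groups were compared with edgeR's quasi-likelihood F test (2-sided, prior count 0.125, no covariate, 2 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Normalised CPM were computed here from the deposited counts and the TMM-scaled library sizes, and are given as mean ± SD over 2 libraries. The standard error of a log2 fold change was taken as its size divided by the square root of F. The common biological coefficient of variation was 0.067. Replicates were compared by a chi-square statistic over genes with at least 20 counts, which gave 3.37 per degree of freedom between the controls and 11.5 between the libraries labelled knockout, so neither pair was a repeat of 1 library.

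Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, lists with at least 3 tested members, Benjamini-Hochberg over 27 lists), again with the correlation estimated, and with fry. The 27 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists share few genes: Lef1 is in the epiblast and Wnt lists, Uhrf1 in the silencing and S-phase lists and Rpl10l in the germline and ribosomal protein lists. Named genes are Ssrp1, Supt16 and Usp7; the 10 largest rises and 10 largest falls among genes past the threshold with at least 1 CPM in the higher group, groups that did not overlap and a symbol without the form of a predicted model, pseudogene (-ps) or identifier, whatever the annotated type; and for each list the 3 members with the smallest adjusted p past the threshold, or the 2 most abundant where none passed. 1 gene that met the rule is not reported here. A gene named otherwise is said to be chosen after its values were seen. Chromosome medians were compared with 100000 random draws of genes.

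Before use, the tests were tested on simulated data: counts for the 17482 genes were drawn from the real means, library sizes and dispersions for the comparison of knockout against control, with 200 genes changed. Of 50 genes changed at each size, edgeR recovered 32 at 1.5-fold, 36 at 2-fold, 48 at 4-fold and 48 at 8-fold, with 6 calls among the 17282 unchanged genes. DESeq2 recovered 23, 32, 48 and 46. With no gene changed, edgeR made 1 call. A simulated list of 30 genes shifted by 0.5 log2 units had a camera p of 1.4e-92, and 0.0018 with an estimated correlation. Genes were drawn independently of each other, and the changed and listed ones were taken from genes above a minimum mean count. The simulation therefore does not show how the tests behave for correlated lists, for genes with few counts or where many genes change.

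Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, scaling by library size alone, TMM without small structural RNA, microRNA and mitochondrially encoded genes, no filter on low counts, a filter of 5 CPM in 2 libraries, a robust prior, the replicate number as a block, lists without predicted models and near-identical families, and each library left out in turn. Added after the data were seen were TMM without the ribosomal-RNA-like genes as well, and offsets for exonic length alone and for exonic length with GC content. Figures were drawn with matplotlib 3.10.9.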

Results

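The transcriptome of mouse E14 embryonic stem cells, a feeder-independent line grown here in serum with LIF, was measured by strand-specific sequencing of ribosomal-RNA-depleted total RNA. There were 2 libraries of wild-type cells, called control 1 and 2 here, and 2 libraries of cells in which Ssrp1 had been targeted with Cas9. Ssrp1 and Supt16 encode the subunits of FACT, a histone chaperone that helps RNA polymerase pass through nucleosomes. Total gene counts were 22611434 and 25344190 in the controls and 22855451 and 23030224 in the libraries labelled knockout. A count above 0 was found for 23497 and 23647 symbols in the controls and for 24721 and 24765 symbols in the libraries labelled knockout. The ribosomal-RNA-like genes Gm26917 and Gm42418 together took 9.72% and 10.3% of the counts in the controls, against 6.30% and 4.64% in the libraries labelled knockout. Mitochondrially encoded transcripts took 1.34% and 1.26% in the controls and 1.48% and 1.81% in the libraries labelled knockout. These shares differed by group and stand beside every comparison given here. The labels do not say whether the 2 libraries of a group came from separate cultures or clones, so the p-values measure the spread between these samples, which may be technical.

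The targeted gene itself was not lower. Ssrp1 (chromosome 2, 85037234 to 85047109, mm10) was at 282.2 and 305.7 CPM (normalised counts, scaled to a common library size) in the controls and at 305.5 and 327.3 CPM in the libraries labelled knockout. Its log2 fold change was 0.11 ± 0.06 (SE, n = 2 per group), with an adjusted p of 0.226 by edgeR's quasi-likelihood test. The call depended on single choices: the adjusted p was 0.031 with scaling by library size alone (log2 fold change 0.19) and 0.011 without the knockout replicate 1 library (0.16). A small Cas9 lesion can leave the transcript in place, and counts per gene do not show one, so the transcript level does not check the labels. The treated samples are therefore called the libraries labelled knockout throughout. Supt16, the partner subunit, was at 891.4 ± 12.8 CPM in controls and 1015.0 ± 54.1 CPM in the libraries labelled knockout (SD, n = 2), a log2 fold change of 0.19 ± 0.06 with adjusted p 0.018 by edgeR. That call was lost without control 1 (adjusted p 0.235) and without control 2 (adjusted p 0.139). Usp7, a ubiquitin-specific protease named in the treatment description, rose from 534.0 ± 7.68 to 706.9 ± 10.2 CPM (log2 fold change 0.40 ± 0.06, edgeR adjusted p 2e-05). The description also mentions an empty vector used for wild-type cells in a Usp7 knockdown, with puromycin selection, and it does not say whether these controls received it.

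**Figure D1:**
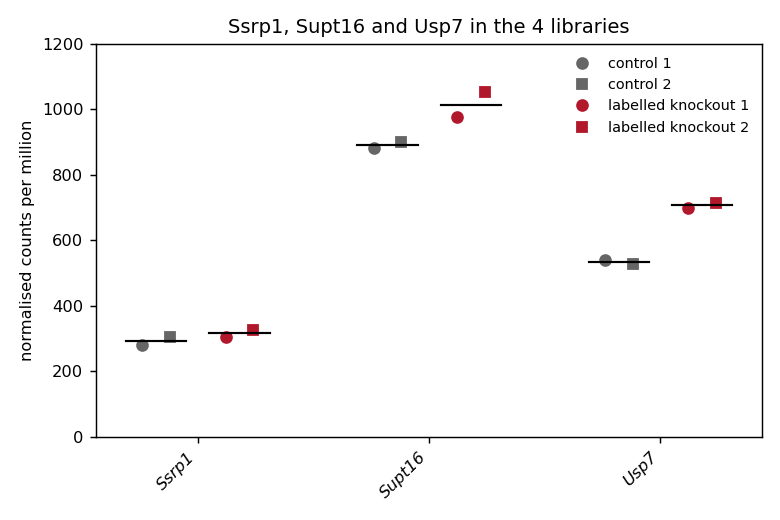
Normalised CPM (vertical axis, from 0) of Ssrp1, Supt16 and Usp7 in each of the 4 libraries, with a horizontal bar at each group's mean. The Ssrp1 means lie at 294.0 and 316.4 CPM and their points differ little from group to group, while Usp7 lies higher in both libraries labelled knockout.

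The comparison of the libraries labelled knockout with the controls asks how the transcriptome stands after Ssrp1 was targeted. Genes of the 2-cell-like state, which are active in the early embryo and in rare cells of an embryonic stem cell culture, had the largest median rise of the 27 gene lists. The imprinted noncoding RNAs Rian and Meg3 of the Dlk1-Dio3 region were at log2 fold changes of -2.36 and -2.11. In addition, 33 of 63 replication-dependent histone genes and 38 of 83 ribosomal protein genes were called lower. With an estimated correlation 0 of the 27 lists passed camera (adjusted p 0.255, 0.346 and 0.508 for the 2-cell-like, histone and ribosomal protein lists). Of 17482 genes tested, 2877 were higher and 3000 lower at an adjusted p under 0.05 (edgeR), of which 850 and 563 changed by at least 1 log2 unit. Of the calls 48.95% were rises, and with scaling by library size alone this share was 63.7% (3887 higher, 2215 lower). The groups did not overlap for 5871 of the 5877 called genes and for 66.6% of all tested genes, where chance gives 33.3%. Without control 1 the number of higher genes was 1915, and DESeq2 called 1977 lower genes.

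Of 52 members of the 2-cell-like state list with a symbol in these data, 37 were tested. Of these 36 rose and 0 fell, both over all genes tested and adjusted over the list alone. Members with few or no counts in the controls passed the filter only through the libraries labelled knockout. Such members could not be called lower, so these counts are in part set by the filter. Zscan4c, a member of the Zscan4 family that marks this state and acts at telomeres, rose from 0.195 ± 0.045 to 18.9 ± 2.25 CPM (log2 fold change 6.57 ± 0.27, edgeR adjusted p 4.2e-13). Gm21761 went from 0.150 ± 0.019 to 31.3 ± 5.40 CPM (log2 fold change 7.65 ± 0.26, adjusted p 3.3e-14). For 12 tested members no count was seen in either control, so that only a lower bound on the fold, against a floor of 3 counts over the group, can be given. Usp17lc had 316 counts in the libraries labelled knockout and was at least 103.9-fold higher, Zscan4b was at least 52.6-fold higher with 160 counts, and Zfp352 at least 25-fold higher with 76 counts. Usp17le, with 3 counts in the controls and 796 in the libraries labelled knockout, had a ratio of 261.8 (95% counting interval 89.3 to 1272). Zscan4e had 1 and 456 counts (ratio 449.9, interval 80.3 to 17809), Usp17lb 1 and 403 (397.6, 71.0 to 15744), and Usp17la 1 and 340 (335.5, 59.8 to 13289). Duxf3, which encodes the Dux factor able to switch this state on, had 0 and 0 counts in the controls and 5 and 11 in the libraries labelled knockout, too few for the test; it was chosen after its values were seen. The tested member that did not rise was Zfp54 (log2 fold change -0.45 ± 0.22, edgeR adjusted p 0.1249), also chosen after its values were seen.

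**Figure D2:**
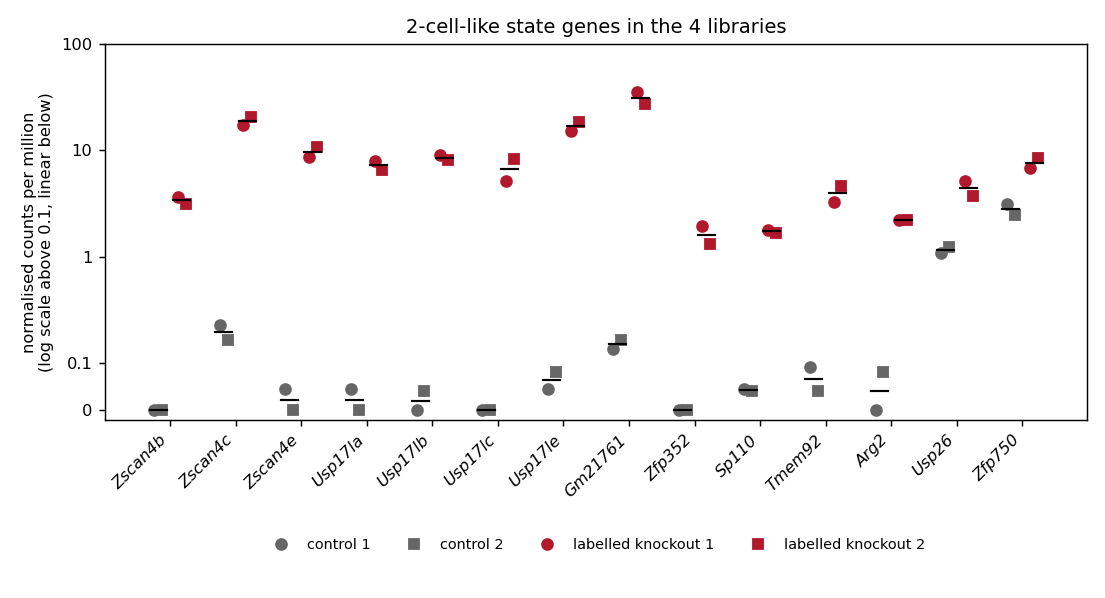
Normalised CPM of 14 members of the 2-cell-like state list in each of the 4 libraries (vertical axis logarithmic above 0.1 and linear below), with a bar at each group's mean. All 14 lie higher in both libraries labelled knockout than in both controls, from Zfp750 (2.79 against 7.58 CPM) to Usp17lc (0 against 6.69 CPM).

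The median log2 fold change of the 37 members was 7.36, and 5.72 with members that had 3 counts or fewer in the controls set to their bound or count ratio. The list stood above all other genes by camera (adjusted p 5.9e-78 with a preset correlation of 0.01). With an estimated correlation, 0.10 for this list, the adjusted p was 0.255. Tested against no change, and not against other genes, the list had an adjusted p of 0.014 by fry. The medians and these list tests, like the counts of calls, are in part set by members that passed the filter only through the libraries labelled knockout. The Zscan4, Usp17l, Tdpoz and related families have near-identical copies, so the split of reads among their members is uncertain. At a filter of at least 5 CPM in 2 libraries the number of higher members was 17, because fewer members were tested.

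Among the largest rises outside this list were D13Ertd608e (at least 46.4-fold, 0 against 141 counts), Kdm4dl, annotated as an unprocessed pseudogene (at least 27-fold, 82 counts), Abcb5, a membrane transporter gene (at least 23-fold, 70 counts), and the Y-linked Kdm5d, a histone demethylase gene (at least 23-fold, 70 counts). All 4 had no count in either control. The X-linked Rhox and Xlr families, homeobox and lymphocyte-regulated gene clusters with germline and placental expression, had 41 members in these data. Of these, 7 were tested, of which 6 rose and 0 fell (7 higher adjusted over the list alone). Members low in the controls met the same limit of the filter. Rhox5 rose from 17.2 ± 1.13 to 69.4 ± 1.91 CPM (log2 fold change 2.01 ± 0.09, edgeR adjusted p 1.7e-12), Rhox6 from 0.587 ± 0.195 to 4.03 ± 0.411 CPM (2.78 ± 0.35) and Xlr3a from 1.25 ± 0.546 to 5.39 ± 0.967 CPM (2.09 ± 0.30). The median was 2.66 and the camera adjusted p 2.7e-08 (adjusted p = 0.308 with an estimated correlation). Other members of these tandem arrays share sequence, which makes values for single members uncertain. Germline genes also rose more often than they fell, 11 higher and 3 lower of 24 tested (12 and 5 adjusted over the list alone; median 0.53, camera adjusted p 0.0051, and adjusted p = 0.411 with an estimated correlation). Tuba3a, a testis tubulin gene, rose from 4.74 ± 0.349 to 47.2 ± 4.65 CPM, and the meiotic gene Hormad1 from 8.56 ± 0.784 to 21.8 ± 4.17 CPM. Smc1b, a meiotic cohesin gene, fell from 76.4 ± 1.45 to 33.9 ± 2.09 CPM.

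Pluripotency genes moved both ways. Of 28 naive pluripotency genes tested, 7 rose and 14 fell (8 and 14 adjusted over the list alone), with a median log2 fold change of -0.15. With scaling by library size alone 9 were higher and 11 lower, and the median was -0.07. Fgf4, a growth factor gene that primes cells for differentiation, fell from 208.7 ± 1.32 to 107.0 ± 4.44 CPM (-0.96 ± 0.07, edgeR adjusted p 8.7e-10), and Tcl1, a cofactor of Akt, from 144.2 ± 0.109 to 81.4 ± 3.78 CPM (-0.83 ± 0.07, adjusted p 1.4e-08). Dppa3, a maternal factor also found in germ cells and early embryos, went the other way, from 2.56 ± 0.479 to 13.6 ± 1.54 CPM (2.40 ± 0.19, adjusted p 7.6e-09). The camera adjusted p of the list was 0.044, and adjusted p = 0.349 with an estimated correlation, and it missed the threshold without control 1 (0.098) and without control 2 (0.075). Leaving out either control also left 4 members higher. Of 16 formative and primed epiblast genes tested, 9 rose and 1 fell, with and without adjustment over the list alone (median 0.59, camera adjusted p 3.2e-05, and adjusted p = 0.349 with an estimated correlation). The DNA methyltransferase gene Dnmt3b rose from 98.1 ± 7.64 to 245.0 ± 17.7 CPM (1.32 ± 0.07, adjusted p 3.9e-11), Grhl2 from 14.8 ± 1.25 to 30.9 ± 1.32 CPM and Lef1 from 2.27 ± 0.896 to 7.16 ± 1.53 CPM.

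Markers of other cell types were measured in the same way. Of 18 primitive endoderm genes tested, 11 rose and 1 fell (13 and 1 adjusted over the list alone; median 0.76, camera adjusted p 8.3e-08, and adjusted p = 0.308 with an estimated correlation). The endocytic receptor gene Lrp2 rose from 68.9 ± 1.99 to 116.0 ± 5.01 CPM, the basement membrane collagen gene Col4a1 from 15.1 ± 0.768 to 34.2 ± 2.95 CPM, and the endocytic adaptor gene Dab2 from 2.61 ± 0.345 to 10.8 ± 1.72 CPM. Of 14 neuroectoderm and neuronal genes tested, 1 rose and 6 fell (1 and 8 adjusted over the list alone; median -0.54, camera adjusted p 0.0017, and adjusted p = 0.346 with an estimated correlation). The adhesion gene Ncam1 fell from 84.5 ± 3.21 to 16.0 ± 2.02 CPM (-2.40 ± 0.10, edgeR adjusted p 2.2e-13) and the microtubule gene Map2 from 19.6 ± 0.204 to 10.0 ± 0.773 CPM, while the intermediate filament gene Nes rose from 12 ± 0.937 to 24.1 ± 0.626 CPM. Neither trophoblast genes (3 higher and 2 lower of 10 tested, median 0.13, camera adjusted p 0.254) nor mesendoderm genes (1 higher and 1 lower of 10, median 0.29, camera adjusted p 0.492) stood apart as a list. Among trophoblast genes Fgfr2 rose from 11.5 ± 0.513 to 29.2 ± 0.728 CPM and the imprinted Peg10 from 662.7 ± 9.40 to 1044 ± 65.5 CPM, and Lgals3 fell from 20.5 ± 1.80 to 11.0 ± 0.498 CPM. The mesendoderm calls, Kdr at 0.211 and 0.786 CPM and Bmp4 at 26.9 and 21.7 CPM (both edgeR adjusted p 0.029), were lost under DESeq2 (adjusted p 0.198 and 0.130). Kdr was also lost without any 1 of the 4 libraries and Bmp4 without control 1 (0.289) or knockout replicate 2 (0.056). Fibroblast and feeder cell markers had 2 higher and 1 lower of 7 tested (median -0.14, camera adjusted p 0.833). Vim fell from 111.2 ± 0.506 to 69.6 ± 2.23 CPM, whereas Tagln rose from 0.612 ± 0.288 to 2.10 ± 0.183 CPM and Col5a2 from 0.170 ± 0.048 to 0.996 ± 0.017 CPM.

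Imprinted genes, which are expressed from 1 parental copy, included Rian, the gene with the smallest adjusted p of all tested. Of 22 tested, 10 fell and 3 rose, with and without adjustment over the list alone (median -0.17, camera adjusted p 6.6e-11, and adjusted p = 0.346 with an estimated correlation). The falls include Rian, Meg3 and Mirg (log2 fold change -1.78, chosen after its values were seen), noncoding RNAs of 1 region that are not independent. The list was not tested without them, so its camera result does not show a fall of imprinted genes as a class. The noncoding RNA Rian (chromosome 12, 109603940 to 109661716, mm10) fell from 828.8 ± 6.21 to 160.9 ± 0.589 CPM (-2.36 ± 0.06, edgeR adjusted p 6.2e-16). Its neighbour Meg3 (109541001 to 109571726) fell from 188.1 ± 8.34 to 43.4 ± 2.24 CPM (-2.11 ± 0.07, adjusted p 3.3e-14). Both are transcribed from the maternal copy of the Dlk1-Dio3 region. The microRNA gene Mir341, inside Rian, was among the 10 largest falls (59 and 8 counts, -2.86 ± 0.64, adjusted p 0.0017), and its value rested on few counts: the log2 fold change was -2.08 without knockout replicate 1 and -4.72 without knockout replicate 2. Mest, expressed from the paternal copy on chromosome 6, fell from 117.5 ± 3.00 to 40.6 ± 2.22 CPM (-1.53 ± 0.08, adjusted p 5.7e-12).

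**Figure D3:**
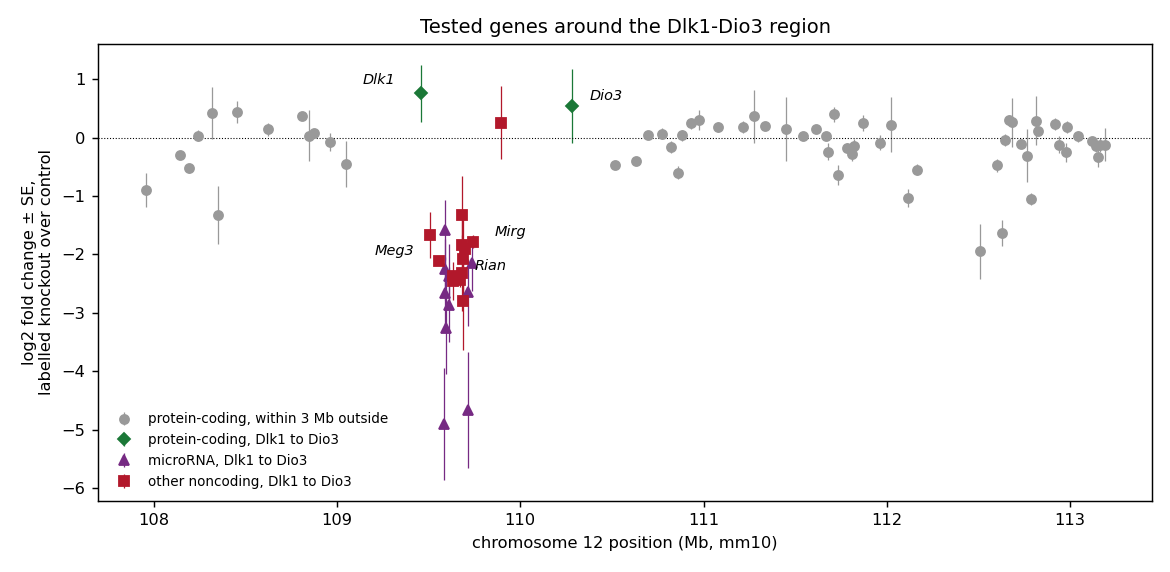
Log2 fold change with its SE (vertical axis) of each tested gene against its position on chromosome 12 in Mb (horizontal axis, mm10), for genes between Dlk1 and Dio3 and for protein-coding genes within 3 Mb outside them. Of the 23 noncoding genes between Dlk1 and Dio3, 21 were lower, with a median of -2.32, while the 62 protein-coding genes outside had a median of -0.05. Noncoding members with few counts in the libraries labelled knockout passed the filter only through the controls and could hardly be called higher.

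The largest falls by the naming rule were of genes from varied classes. Chac1, which degrades glutathione and is induced by amino acid stress, fell from 16.6 ± 4.08 to 1.63 ± 0.429 CPM (-3.34 ± 0.22, edgeR adjusted p 5.2e-10). The proapoptotic gene Hrk fell from 11.4 ± 2.03 to 1.35 ± 0.283 CPM (-3.07 ± 0.23), and the calcium pump gene Atp2b2 from 24.2 ± 0.237 to 3.48 ± 0.524 CPM (-2.80 ± 0.15). Catsperz, Gsx2, Cacna1c, Gpr139 and Grin2c lay between 1.51 and 2.92 CPM in controls and between 0.128 and 0.405 CPM in the libraries labelled knockout, with log2 fold changes from -3.51 to -2.84. Leaving out knockout replicate 1 moved Gsx2 to -3.82 and Grin2c to -3.76. In the ATF4 and amino acid stress list, 10 of 18 tested members fell and 3 rose (11 and 3 adjusted over the list alone; median -0.26, camera adjusted p 6.9e-04, and adjusted p = 0.512 with an estimated correlation). Without control 1 the number of falls was 6. Atf4 itself, the transcription factor gene of this response, fell from 208.6 ± 9.64 to 123.4 ± 5.16 CPM, and Aldh1l2, of mitochondrial folate metabolism, from 9.80 ± 1.79 to 3.45 ± 0.346 CPM.

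Histone and replication genes were called lower more often than higher. Of 63 replication-dependent histone genes tested, 33 fell and 1 rose (34 and 3 adjusted over the list alone; median -0.37, camera adjusted p 3.6e-08, and adjusted p = 0.346 with an estimated correlation). The linker histone gene H1f5 fell from 285.6 ± 5.49 to 166.6 ± 11.2 CPM (-0.78 ± 0.07, edgeR adjusted p 2.2e-08), H3c11 from 128.4 ± 7.30 to 76.4 ± 7.13 CPM and H1f3 from 514.8 ± 29.1 to 342.9 ± 2.09 CPM. Members of this family share near-identical sequence, so their single values are uncertain. Of 31 S-phase and DNA replication genes, 12 fell and 0 rose (13 and 0 adjusted over the list alone; median -0.15, camera adjusted p 0.0090, and adjusted p = 0.346 with an estimated correlation). The DNA ligase gene Lig1 fell from 298.0 ± 8.68 to 205.9 ± 15.5 CPM, the helicase subunit gene Mcm6 from 490.0 ± 14.1 to 369.2 ± 30.1 CPM and Gins2 from 49.2 ± 1.32 to 35.4 ± 1.47 CPM. The number of falls was 7 without control 2. With scaling by library size alone 3 of these genes were higher and 8 lower (median -0.07), and of the replication-dependent histone genes 5 were higher and 29 lower (median -0.29). G2 and mitosis genes did not stand apart (9 higher, 3 lower of 24, median 0.03, camera adjusted p 0.324). Aurka rose from 161.1 ± 6.97 to 220.0 ± 30.6 CPM, and the smaller rises of Plk1 (log2 fold change 0.30) and Cenpf (0.25) were lost without control 1 (edgeR adjusted p 0.052 and 0.098), which left 2 of the list's genes higher. Histone variant genes had 3 higher and 1 lower of 11 (median -0.02, or 0.06 with scaling by library size alone, camera adjusted p 0.933). H2ax, the variant phosphorylated at DNA breaks, fell from 195.6 ± 2.53 to 143.0 ± 1.95 CPM, H2az1 rose from 272.7 ± 1.72 to 355.2 ± 10.8 CPM, and the rise of H1f10 (0.53 ± 0.13) was lost without knockout replicate 2 (adjusted p 0.055).

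**Figure D4:**
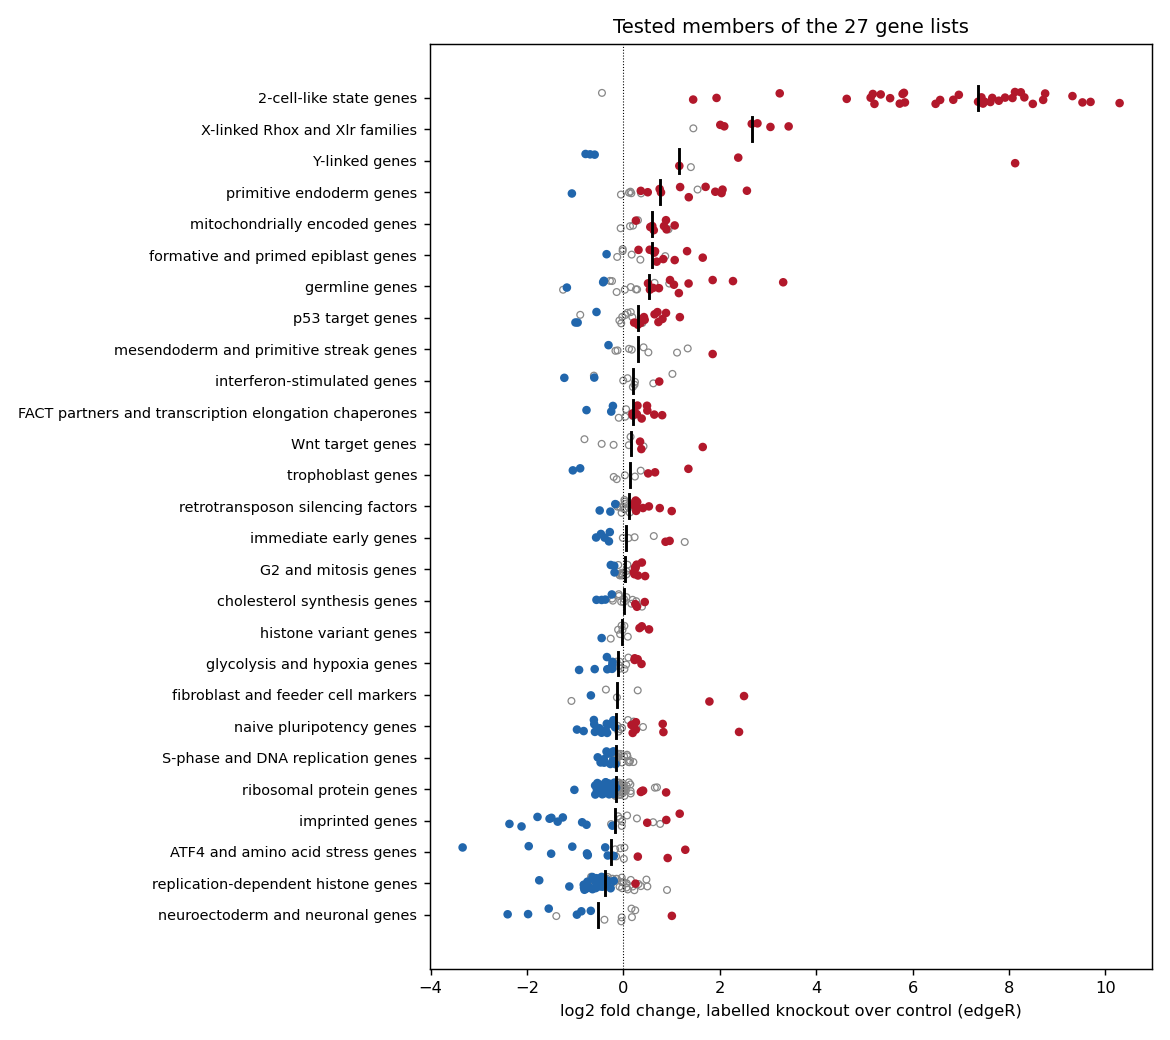
Log2 fold change (horizontal axis, libraries labelled knockout over controls) of every tested member of the 27 gene lists, with filled points for genes past the threshold (red higher, blue lower), open points for the others and a black bar at each list's median. The 2-cell-like state list lies apart at a median of 7.36, and most medians lie between -0.54 and 0.76.

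Of 83 ribosomal protein genes tested, 38 were lower and 4 higher (39 and 5 adjusted over the list alone; median -0.16, camera adjusted p 3.2e-05, and adjusted p = 0.508 with an estimated correlation). With scaling by library size alone 31 were lower and 7 higher, and the median was -0.08. Rpl10a fell from 927.0 ± 3.74 to 616.9 ± 19 CPM, Rpl37a from 331.7 ± 0.707 to 226.5 ± 13.5 CPM and Rps2 from 1743 ± 50.9 to 1262 ± 58.4 CPM; reads shared with processed pseudogenes make such values uncertain. Mitochondrially encoded genes were higher, 8 of 13 with 0 lower (9 and 0 adjusted over the list alone; median 0.60, camera adjusted p 1.2e-04, and adjusted p = 0.512 with an estimated correlation). The values differed between the libraries labelled knockout, with mt-Nd1 at 473.7 ± 7.23 CPM in controls against 873.5 ± 200.01, mt-Nd4 at 213.0 ± 26.9 against 444.8 ± 153.3 and mt-Nd2 at 280.0 ± 11.2 against 520.2 ± 171.8 CPM. With a robust prior the calls of mt-Nd4 and mt-Nd2 were lost (edgeR adjusted p 0.183 and 0.199). Genes for the partners of FACT and other elongation chaperones had 10 higher and 3 lower of 18 (11 and 3 adjusted over the list alone; median 0.20, camera adjusted p 0.024, and adjusted p = 0.349 with an estimated correlation). Ctr9, of the PAF1 complex, rose from 87.8 ± 5.09 to 153.4 ± 8.32 CPM and the histone chaperone gene Nap1l1 from 811.5 ± 17.8 to 1264 ± 15.5 CPM, while the remodeller gene Chd2 fell from 268.9 ± 9.75 to 158.0 ± 0.883 CPM. Leaving out either control left 6 higher and 1 lower, and without control 2 the camera adjusted p was 0.075.

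Genes that silence retrotransposons had 11 higher and 3 lower of 25 tested (11 and 4 adjusted over the list alone; median 0.10, camera adjusted p 0.024, and adjusted p = 0.512 with an estimated correlation). Atrx, a chromatin remodeller gene, rose from 358.5 ± 1.48 to 604.4 ± 26.2 CPM, the zinc finger repressor gene Zfp809 from 36.5 ± 0.872 to 73.0 ± 9.93 CPM and Hdac1 from 131.9 ± 0.051 to 190.1 ± 21.9 CPM. Without control 1 the number of rises was 5 and the camera adjusted p 0.098, and without control 2 there were 7 rises. Of 25 p53 target genes, 13 rose and 3 fell (15 and 3 adjusted over the list alone; median 0.30, camera adjusted p 7.0e-04, and adjusted p = 0.508 with an estimated correlation). The p53 inhibitor gene Mdm2 rose from 118.8 ± 12.5 to 219.2 ± 5.97 CPM, Plk2 from 23.1 ± 1.63 to 52.0 ± 3.23 CPM and Ccng1 from 281.0 ± 15.8 to 439.5 ± 15.2 CPM.

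The Y-linked genes split, with 3 higher and 3 lower of 7 tested (camera adjusted p 0.915). Ddx3y fell from 66.5 ± 0.359 to 38.6 ± 2.23 CPM, Uty from 92.9 ± 5.07 to 57.5 ± 5.85 CPM and Eif2s3y from 98.3 ± 2.70 to 65.0 ± 0.070 CPM, whereas Kdm5d rose from no count. The list's median was 1.16 while the direction of its camera test was down, so the measures differ in sign. The remaining lists did not pass camera. Interferon-stimulated genes had 1 higher and 2 lower of 11 (median 0.20, adjusted p 0.989, up by camera and down by fry): Bst2 rose from 14.04 ± 0.877 to 23.5 ± 1.71 CPM, Xaf1 fell from 14.1 ± 0.479 to 6.01 ± 1.48 CPM and Ddx58 from 30.5 ± 1.34 to 20.05 ± 1.31 CPM. Wnt target genes had 3 higher and 0 lower of 9 (median 0.15, adjusted p 0.269), among them Lef1, Ccnd1 (61.0 ± 1.07 and 78.8 ± 0.655 CPM) and Znrf3, whose call was lost without control 2 (edgeR adjusted p 0.291) and under DESeq2 (0.058). Glycolysis and hypoxia genes had 4 higher and 7 lower of 20 (median -0.11, adjusted p 0.118, and 0.035 without control 1 or 0.037 without knockout replicate 1), with falls of Vegfa from 61.3 ± 2.10 to 32.4 ± 1.19 CPM, Pfkp from 1099 ± 20.6 to 727.1 ± 5.11 CPM and Aldoa from 1994 ± 80.2 to 1581 ± 44.0 CPM. Trophoblast genes likewise reached an adjusted p of 0.037 without knockout replicate 1. Cholesterol synthesis genes had 3 higher and 4 lower of 20 (median 0.01, direction down by camera, adjusted p 0.833), the falls including Insig1 (155.2 ± 18.2 to 105.4 ± 8.67 CPM), Cyp51 (105.9 ± 3.39 to 77.4 ± 5.59 CPM) and Lss (92.4 ± 2.56 to 71.2 ± 3.75 CPM). Immediate early genes had 2 higher and 5 lower of 12 (median 0.05, direction down by camera, adjusted p 0.974): Ier3 rose from 9.10 ± 0.938 to 17.7 ± 0.553 CPM and Myc from 7.37 ± 0.028 to 13.5 ± 1.06 CPM, and Spry4 fell from 199.3 ± 5.95 to 152.0 ± 18.4 CPM. The histone variant list also had a median below 0 and a camera direction of up.

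Over the 27 lists, 16 passed camera with the preset correlation, 9 up and 7 down. In that form camera takes its degrees of freedom from the number of genes, and genes are not replicates. The preset correlation was 0.01, while the estimated ones ranged from -0.16 (fibroblast and feeder cell markers) to 0.61 (mitochondrially encoded genes). With an estimated correlation 0 passed, and fry, which tests against no change, called 10. Some lists passed camera with the preset correlation and missed the threshold by fry. These were the germline (fry adjusted p 0.063), p53 target (0.078), retrotransposon silencing (0.078) and ribosomal protein (0.078) lists. The ATF4 and amino acid stress list (fry adjusted p 0.11) and the mitochondrially encoded genes (0.164) missed it too. Scaling by library size alone also raised the medians of other lists: to -0.09 for imprinted genes, -0.05 for fibroblast and feeder cell markers, -0.03 for glycolysis and hypoxia genes, 0.09 for cholesterol synthesis genes and 0.12 for G2 and mitosis genes. The medians of immediate early genes, genes that silence retrotransposons, trophoblast genes and Wnt target genes were then 0.13, 0.19, 0.22 and 0.23. Of the mesendoderm genes 3 were then higher and 0 lower, and of the cholesterol synthesis genes 5 and 3. No whole chromosome stood far from the rest: over 20 chromosomes the medians lay between -0.06 on chromosome 17 (831 genes, permutation adjusted p 0.0022) and 0.06 on the X chromosome (541 genes, permutation adjusted p 0.079). These permutations move genes among chromosomes in the same libraries and describe these libraries only, since genes are not replicates.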

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

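TMM without the ribosomal-RNA-like genes and the offsets for length and for length with GC content were chosen after the results were seen; the other settings were planned. Both settings of TMM without small structural RNA also left out microRNA and all mitochondrially encoded genes, so that Mir341, mt-Nd1, mt-Nd2 and mt-Nd4 were not tested there. No named gene reversed its direction in any setting in which it was tested. Of 100 named genes other than Ssrp1, 91 kept their direction and side of the threshold in every setting in which they were tested, and 9 lost their call in at least 1. Most of these genes were chosen from the same libraries by a large fold or a small adjusted p, which favours keeping the call. The count therefore does not measure how stable the calls are over all genes. The offset for length alone gave 2983 higher and 2900 lower genes, and the offset for length with GC content 2961 and 2875. With length alone 4 naive pluripotency genes were higher, and with length and GC content 1 gene of the FACT partners was lower. DESeq2 called fewer genes, 1935 higher, 1977 lower and 371 lower by at least 1 log2 unit, and of the 5877 calls it kept 3886 with the same direction; the cause was not tested. At 5 CPM in 2 libraries fewer genes were tested (11033), which left 187 higher and 208 lower by at least 1 log2 unit, 17 higher 2-cell-like genes and a chromosome 17 median of -0.039. Scaling by library size alone moved the median of genes above 5 CPM from -0.02 to 0.06 and gave Ssrp1 a log2 fold change of 0.19 (adjusted p 0.031); over all settings with a test its adjusted p ranged from 0.011 to 0.828. An estimated correlation left camera with 2 residual degrees of freedom and 0 lists past the threshold, and fry called 10. Leaving out 1 library, with the lone library assumed to vary like the other group and 1 residual degree of freedom, gave 1915 to 2995 higher genes, the lowest without control 1, and a Ssrp1 log2 fold change of 0.041 to 0.16, past the threshold without knockout replicate 1. The replicate numbers did not pair the samples (correlation of same-numbered deviations 0.008 over tested genes), and with the replicate block 3072 genes were higher and 3216 lower. Depth limits low genes: 77 genes called higher had no count in the controls, so their folds are bounds.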

Other observations

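The genes named in this part were chosen after their values were seen, apart from those the rule names. Of its tests, those of the genes that flank the Dlk1-Dio3 region and of length with GC content were set before their results were seen, and the others after. The offset for length alone had already been run when GC content was added, so the test of length with GC content was not independent of that result. Most of the annotated microRNA genes that were called lay at 2 places in the genome. Sfmbt2, a polycomb-group gene on chromosome 2 (10370510 to 10595253, mm10) whose intron holds a large microRNA cluster, rose from 84.9 ± 9.86 to 308.6 ± 16.7 CPM (SD, n = 2; log2 fold change 1.86 ± 0.08, edgeR adjusted p 4.4e-13). Of the 66 microRNA genes tested inside it, 60 were higher and 0 lower (median 2.67), with 1058 counts in the controls and 6406 in the libraries labelled knockout. All 10 microRNA genes tested between Dlk1 and Dio3 were lower (median -2.66). These 10 had 601 counts in the controls and 108 in the libraries labelled knockout. Of the 66 tested elsewhere, 3 were higher and 1 lower (median 0.13). At both places, members with few counts in 1 group passed the filter only through the other group. Such members could hardly be called in the opposite direction, so these counts of calls are in part set by the filter. Reads in such genes can come from the host transcript, since no step for small RNA is described, and the 66 members inside Sfmbt2 include near-identical copies.

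Of the abundant genes that fell, the smallest adjusted p after that of Rian belonged to the nonmuscle myosin gene Myh9, which fell from 313.6 ± 6.18 to 58.0 ± 6.46 CPM (-2.43 ± 0.08, edgeR adjusted p 1.0e-14). The axonemal dynein gene Dnah8 fell from 500.5 ± 4.46 to 146.3 ± 0.585 CPM, and Txnip, a regulator of glucose uptake, from 1369 ± 38.3 to 417.1 ± 23.8 CPM. On the Y chromosome, Uba1y rose from 6.77 ± 0.044 to 15.1 ± 1.06 CPM and Zfy1 from 0.735 ± 0.692 to 3.76 ± 1.58 CPM (log2 fold change 2.38, 3.90 without control 1 and 1.61 without control 2), while Ddx3y, Uty and Eif2s3y fell by 0.79, 0.69 and 0.60 log2 units. Pseudogenes had 109 higher and 55 lower of 915 tested, and genes awaiting experimental evidence 90 and 44 of 960, against 2432 and 2708 of 13635 protein-coding genes.

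The rise of 2-cell-like genes was set against reads shared between near-identical paralogs, and against more informative reads from a lower ribosomal-RNA-like share. Of 8 members outside such families and predicted models, 7 were called higher, with a median log2 fold change of 4.90. Among them Zfp352, Ubtfl1, Sp110, Tmem92 and Arg2 had 0, 2, 2, 3 and 2 counts in the controls. They passed the filter only through the libraries labelled knockout and could not be called lower, so the median and the count of 7 are in part set by the filter. Usp26 and Zfp750, with 54 and 129 counts in the controls, rose by 1.93 and 1.45 log2 units, while Zfp54, with 233, was not called. The rises of Usp26 and Zfp750, which did not depend on the filter in this way, argue against shared reads as the whole cause for these members. The lower ribosomal-RNA-like share raises the share of all other reads by at most 0.088 log2 units between any pair of libraries. The median of the 37 members, with low ones at their bound or count ratio, was 5.72 (SD 2.13). The difference in size argues against the second. The size of the rise was known when this comparison was set, so its outcome could be foreseen. A biological difference between the groups stays open as a hypothesis. It was not tested whether it may come from the loss of Ssrp1 or from a clone or culture that differs in other ways, and bulk counts do not separate more cells in this state from a higher level per cell.

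The fall of Dlk1-Dio3 noncoding RNAs was set against loss of a chromosome copy or large segment, and against a lower yield of long noncoding RNA as a class. The 62 protein-coding genes within 3 Mb outside the region had a median log2 fold change of -0.053 (SD 0.483). A median of -0.5 or lower had been set as the mark of a lost copy. The 254 other long noncoding RNA genes at 5 CPM or more had a median of -0.033 (SD 0.516), although Malat1 was lower by itself (-0.56 ± 0.05). These values argue against a lost copy, or a lost segment that spans the flanks, in most cells, and against a lower yield of the class. A loss in some of the cells, or of a segment that ends near the region, was not tested by this median. A deletion limited to the region, a change of imprint in a clone and an effect of losing Ssrp1 remain possible and were not tested. Dlk1 and Dio3 (0.76 ± 0.49 and 0.55 ± 0.63) were not called (edgeR adjusted p 0.246 and 0.543), and their values depended on single libraries. Without knockout replicate 1 their log2 fold changes were 1.29 and 1.02, and without knockout replicate 2 they were -0.09 and -0.19.

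The fall of replication-dependent histone genes was set against bias of length or GC content, a lower yield of RNA without poly(A) tails and fewer cells in S phase. After an offset for exonic length and GC content, for which 62 of the 63 genes had values, their median was -0.384 with 33 lower, against -0.375 before, and with length alone it was -0.463 with 37 lower. Not every length used matches its gene: H1f3 had an exonic length of 7425 bases but lies at 23555032 to 23555807 on chromosome 13. The offsets are uncertain to that extent. The 208 snRNA, snoRNA and scaRNA genes had a median of 0.142 (SD 0.712), with 14 higher and 6 lower. The lower ones included Gm24564, AF357341, Gm25856, Gm23787 and Gm25224, snoRNA genes between Dlk1 and Dio3. As a class the 208 genes were not lower. The distance of their median to the histone median was within the spread of single genes, which is not the error of a median. By that measure the values do not decide, and a lower yield of RNA without poly(A) tails stays open. The S-phase and DNA replication list was lower as a set (median -0.150, camera and fry adjusted p 0.0090 and 0.014, and adjusted p = 0.346 with an estimated correlation; median -0.07 with scaling by library size alone), so that fewer cells in S phase is a candidate explanation, as a hypothesis, with the share of cells in each phase not measured. An effect of losing Ssrp1 on histone transcription stays open and untested.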
